A study of Mus musculus with 18 samples.

How the data were processed

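The samples were cultures of MEL cells, a mouse erythroleukemia line whose cells start to make hemoglobin when dimethyl sulfoxide (DMSO) is added. Cells were taken before treatment (day 0) and after 5 days in 2% DMSO (day 5). For each day there were 2 biological replicates, per the labels, of PU.1 ChIP-seq, stranded RNA-seq, DNase-seq and ChIA-PET with an antibody against RNA polymerase II (4H8). ChIA-PET joins DNA ends that lie together in an immunoprecipitate and so lists pairs of contacting regions. There was also 1 input control of the PU.1 ChIP per day, which was not analysed here. Groups and replicate numbers came from the sample titles.

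The RNA values were FPKM per gene and library, computed by the authors and deposited as 1 table. Bowtie and the genome build mm9 are named in the submitters' processing notes, while the quantifier is not given in the sources used here. The table listed 26599 genes with a symbol and an Ensembl-style ID. A group of 324 rows shared a symbol with another row, so rows with a repeated symbol were identified by ID. FPKM carry no read counts, so the depth of each library is unknown and no counting interval was given. An FPKM of 0, or of nearly 0 in members of gene families, may be a failed estimate, and such genes are described as listed at 0. PU.1 peaks of each replicate carried a fold enrichment (a ratio) and a −log10 p from the peak caller as deposited, and both are the authors' values. Bowtie 1.0.0, MACS2 2.0.10 and mm9 are named for this assay in the submitters' processing notes. The authors also deposited 1 list per day merged over both replicates by IDR. Its IDR column holds the authors' irreproducible discovery rate, a q-value per peak made by comparing both replicates before deposition, per the file headers. It stayed under 0.05 for every peak, and the score of that list lay within 0.01 of the mean −log10 p of overlapping peaks of both replicates for 13941 of 14064 day 0 peaks and 3507 of 3530 day 5 peaks. DNase hypersensitive sites were deposited per replicate with a score of at least 2. The authors also deposited 1 list per day of the intersection of both replicates, 1 list consolidated over both days, and 1 list of footprints per day with a score of −20 or lower. The intersected lists carry the score of replicate 1, within 0.01 for every site. Bowtie, bedtools and mm9 are named for the DNase files in the submitters' processing notes, with no versions and no cutoffs. For ChIA-PET, vertices were built from DNase sites merged with polymerase II and cohesin peaks and widened to 1 kb, per the labels, and a set of 3 kb vertices was deposited as well. Edges between vertices were deposited by the authors as 1 list per day with a score whose definition is not given in the sources used here. It is not a count of paired tags. It was negative for every edge between chromosomes and positive for every edge within one.

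From the FPKM, genes with at least 1 FPKM in at least 2 libraries were kept, which left 10736 genes. Values were transformed as log2(FPKM + 1), so fold changes understate the change of low genes. Day 5 was compared with day 0 by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, intercept and day), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 27 gene lists were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Of 751 listed symbols, 744 were found, partly through older symbols. Lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, and again with a correlation estimated per list. limma's fry, which tests whether a list's genes move on balance one way, was run beside it. The named genes were, first, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 FPKM on 1 or both days and both day 5 libraries on the same side of both day 0 libraries, leaving out predicted genes, clone names and small RNAs. Next came up to 4 called members of each list, up to 2 in each direction where both existed, or the 2 most highly expressed members where none was called. Some genes that this rule names are not reported here. The third part was a fixed set of 17 loci chosen from the assay and the cell type. For regions, the 5 PU.1 peaks with the highest score, the 5 vertices with the most edges and the 5 edges with the highest absolute score were named for each day. The score stands in for the number of paired tags that the rule asked for.

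The fit was tested on simulated data with the means of the 10736 genes of this comparison. The spread of each gene was limma's estimate, already drawn toward the trend over all genes, which suits the method tested. The simulated noise was normal, and 200 of the more highly expressed genes were changed. In the real data 1989 genes passed, so recovery there may differ. Of 100 genes changed by 1 on the log2 scale 11 were recovered, and of 100 changed by 2 there were 79, with 0 of wrong sign and 10 false calls. Regions were compared with bedtools 2.31.1, Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, counting an overlap of at least 1 bp as shared, and the overlap code was tested on made intervals. Shares carry 95% Wilson intervals, which cover counting error only. A background for PU.1 peaks in DNase sites came from 100 random placements on the same chromosomes. Fisher tests on vertices were two-sided and adjusted by Benjamini-Hochberg over 12 tests. Vertices are not independent samples, so these tests describe the lists. Footprints and edges have 1 list per day, so they have no replicate check. Coordinates are mm9 as in the files, counted from 1. No mm9 gene annotation or genome was used here, so the planned joins of PU.1 peaks and edges to genes and the search for GATA1, YY1, CTCF and PU.1 motifs were left out, and regions carry no gene names. The alternatives were other pseudocounts, filters, scalings and overlaps, stricter or equally long lists, 3 kb vertices, a fit with the replicate number as a block, and leaving out each replicate in turn. Removal of mitochondrially encoded genes, equal numbers of edges and the top 50% of edges by score were chosen after seeing the data.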

Results

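MEL cells were profiled before (day 0) and after 5 days in DMSO (day 5) by RNA-seq, PU.1 ChIP-seq, DNase-seq and RNA polymerase II ChIA-PET, with 2 biological replicates per assay and day. The RNA table held 4 libraries whose FPKM summed to between 758150 and 787494, with 10227 to 10601 genes at 1 FPKM or more. Read depth is not given by FPKM or by lists of regions, and so is unknown for every library. On the log2 scale the replicates correlated across genes at 0.964 on day 0 and 0.939 on day 5, and libraries of different days at 0.851 to 0.888. Genes are not independent replicates, so these values only describe the libraries.

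The comparison of RNA asks which genes change as the cells are driven to make hemoglobin. Hba-a1, Hbb-b1 and Hba-a2 were the most abundant on day 5 of the genes that passed the threshold upward. The mitochondrial gene mt-Atp8 was more abundant, at 14891 ± 6674 FPKM on day 0 and 35068 ± 3763 on day 5, but did not pass (limma adjusted p = 0.0787). Alpha globin (Hba-a1) went from 353 ± 104 FPKM on day 0 to 16297 ± 2301 on day 5 (SD, n = 2 in each), 46.2-fold. Reads of the near-identical Hba-a2 are hard to part from its own, so the size of this fold is uncertain. Beta globin (Hbb-b1) went from 727 ± 250 to 9561 ± 1169 FPKM, and Alas2, the erythroid enzyme of the first step of heme synthesis, from 15.2 ± 6.36 to 700 ± 74.2 FPKM. Sfpi1, the gene of the myeloid transcription factor PU.1, fell from 78.2 ± 32.2 to 2.96 ± 0.835 FPKM. Car1, a carbonic anhydrase gene, fell from 969 ± 63.6 to 3.30 ± 0.266 FPKM, and Myb, a transcription factor gene of blood progenitors, from 68.9 ± 14.5 to 1.79 ± 1.02 FPKM. The globin share of all FPKM was 0.217% and 0.134% in the day 0 libraries and 3.98% and 3.75% in the day 5 libraries. Mitochondrially encoded genes took 4.88% and 6.45% on day 0 and 8.46% and 10.3% on day 5. The gene mt-Atp8 alone weighs on these shares, at 10172 and 19611 FPKM in the day 0 libraries and 32407 and 37728 in the day 5 libraries.

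Of 10736 genes tested, 1989 passed an adjusted p of 0.05 in limma, 1150 higher and 839 lower on day 5. The median log2 fold change of all tested genes was 0.15, so the split leans upward with the deposited scaling. After quantile normalization the median was 0.01 and the split was 814 higher and 895 lower. With no filter on low FPKM 237 of 15168 genes passed, 120 higher and 117 lower. Among genes named above, Alas2 (limma adjusted p = 0.0517), Hbb-b1 (0.0688), Hba-a2 (0.0917), Myb (0.0591) and Sfpi1 (0.0661) did not pass then. Hba-a1 (0.0497) and Car1 (0.0431) did. With 1 library left out the fit rested on a lone library for that day, assumed to vary like the other day. Then 0 genes passed in limma without day 0 replicate 1, day 0 replicate 2 or day 5 replicate 1 (3038, 2504 and 3218 at an unadjusted p under 0.05). Without day 5 replicate 2, 13 passed (3440 unadjusted), 2 higher and 11 lower. All 1989 genes kept their direction in these 4 fits, which their selection in the same libraries made nearly certain.

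**Figure D1:**
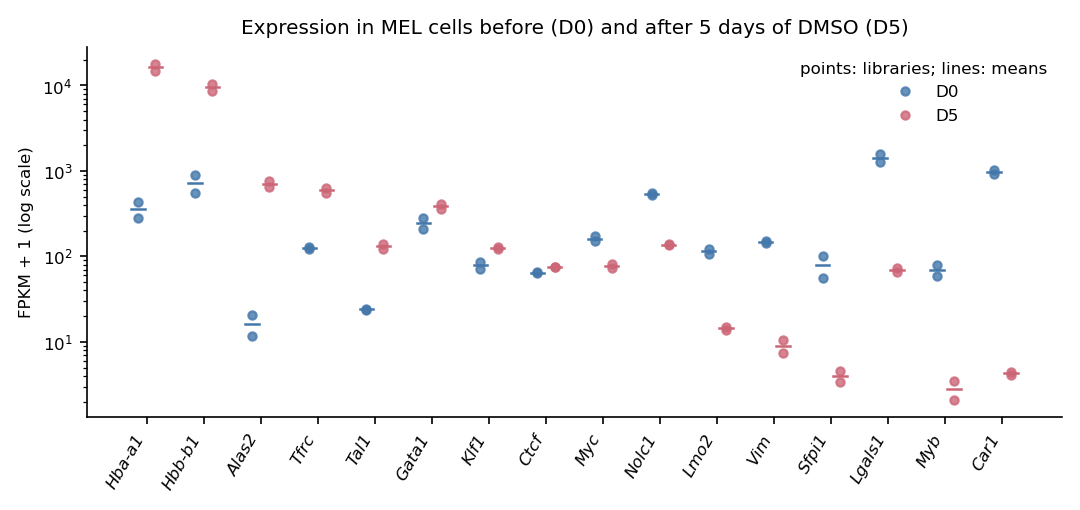
FPKM + 1 (log axis) of 16 named genes in MEL cells on day 0 (blue) and day 5 (red), where points are the 2 libraries of a day and short lines their means. Hba-a1 stands at 353 FPKM on day 0 and 16297 on day 5, while Car1 goes from 969 to 3.30.

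Among the largest increases, beside Hba-a1 (log2 fold change 5.55) and Alas2 (5.49), Apol11b, an apolipoprotein L gene, went from 0.192 ± 0.272 to 91.8 ± 1.52 FPKM (log2 fold change 6.30 ± 0.27 SE, limma adjusted p = 0.0021). Btg2 and Mxd4, both known to restrain proliferation, had log2 fold changes of 4.91 and 4.85, that of Btg2 being 5.56 without day 0 replicate 1 and 4.26 without day 0 replicate 2. Abat, which breaks down GABA, and Smox, which oxidizes spermine, had 4.74 and 4.49. Hba-a2 had 4.45, but its reads are hard to part from those of the near-identical Hba-a1, so the fold of either gene is uncertain. Day 5 replicates 1 and 2 held 17923 and 14670 FPKM of Hba-a1, and 2430 and 5338 FPKM of Hba-a2. One of the Gypc entries (ENSMUSG00000024380.6) had the highest log2 fold change, 7.46, from 0.00526 to 177 FPKM. A second Gypc entry (ENSMUSG00000090523.2) went from 35.2 to 159 FPKM, so reads of this glycophorin gene may have been split unequally and the fold of either entry is uncertain. Hist1h2bn, a histone gene with near-identical copies, is uncertain in the same way (log2 fold change 4.51).

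Among the largest decreases were Car1 (log2 fold change -7.82), Hemt1 (-7.20) and Muc13 (-4.92). Gml fell from 88.9 ± 1.88 FPKM to being listed at 0 in both day 5 libraries. Lgals1, which encodes galectin-1, fell from 1430 ± 204 to 67.7 ± 5.11 FPKM (log2 fold change -4.38 ± 0.18 SE). Rnase6 had a log2 fold change of -4.10 and Anxa2 one of -4.61. Anxa2 differed between the day 5 libraries (4.68 and 0.081 FPKM), had -5.81 without day 5 replicate 1 and -3.42 without replicate 2, and did not pass with a pseudocount of 0.1 (limma adjusted p = 0.0598). An Nme2 entry (ENSMUSG00000020857.5) had -5.52 (-4.22 without day 5 replicate 1 and -6.83 without replicate 2), while a second entry of that symbol (ENSMUSG00000091228.1) had -0.13 with limma's adjusted p = 0.852, so this change is uncertain.

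In each of 5 erythroid lists most genes that passed had risen. Of 6 globin genes tested, 5 rose and 0 fell, also adjusted over the list alone, and the embryonic gene Hbb-y did not pass (1.01 and 0.55 FPKM, limma adjusted p = 0.523). Of 14 heme synthesis genes, 9 rose and 0 fell, among them Abcb10 (log2 fold change 2.58) and Fech (2.39). Adjusted over the list alone, 11 rose and 2 fell. Of 23 genes of the red cell membrane, 17 rose, such as Epb4.2 (4.28) and Slc4a1 (2.15), the band 3 anion exchanger. In this list 2 fell, the glucose transporter Slc2a1 (-2.04) and the early marker Cd24a (-1.21). Of 29 other late erythroid genes, 16 rose, including Hemgn (3.25), and only Car1 fell. Adjusted over the list alone, 17 membrane genes rose and 2 fell, and 18 late erythroid genes rose and 2 fell. Of 16 iron genes, 4 rose, such as the transferrin receptor Tfrc (2.24) and Glrx5 (1.23), and Pcbp1, an iron chaperone gene, fell (-0.69), while adjusted over the list alone 6 rose and 2 fell. Pcbp1 stood close to the threshold (limma adjusted p = 0.0492) and did not pass with a pseudocount of 0.1 (0.0538), quantile normalization (0.153), globin genes removed (0.0549), mitochondrially encoded genes removed (0.0612) or no filter (0.108).

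By camera, adjusted over the lists, globin (adjusted p = 0.00058), heme (0.00058), membrane (2.66e-06) and late erythroid genes (5.47e-05) ranked higher on day 5 than other genes, and iron genes did not pass (0.39). With an estimated correlation the 4 calls were lost, at an adjusted p of 0.362, 0.362, 0.26 and 0.362. No list of any kind passed with an estimated correlation. That estimate rests on 4 libraries, 2 per day, and so is imprecise. By fry, which asks only whether the list moves one way, the adjusted p was 0.0217, 0.0217, 0.0078 and 0.0237, and 0.0318 for iron genes.

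The regulators of the lineage did not move as 1 group. Of 22 erythroid transcription factor and cofactor genes, 3 rose, 3 fell and 16 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.623). Tal1 rose from 23.1 ± 0.367 to 130 ± 14.1 FPKM and Klf3 had a log2 fold change of 0.87. Lmo2, a partner of Tal1, fell from 114 ± 10.3 to 13.4 ± 0.932 FPKM, and Bcl11a, a repressor of fetal globin genes, had a log2 fold change of -2.71. Gata1 had a log2 fold change of 0.66 (limma adjusted p = 0.076) and Klf1 one of 0.68 (0.054). Both passed after quantile normalization, Gata1 at 0.92 (0.0412) and Klf1 at 0.80 (0.0417), and Klf1 also at a filter of 5 FPKM (0.0475). Among factors of chromosome looping named in the series title, Ctcf had 0.21 (0.37) and Yy1 -0.42 (0.463). Yy1 differed between the day 5 libraries, at 36.8 and 83.8 FPKM, and without the lower of these its log2 fold change was 0.16. Of 17 architectural and looping factor genes only Med13 rose (0.90) and 0 fell (camera adjusted p = 0.455), and adjusted over the list alone 0 passed in limma (6 at an unadjusted p under 0.05). Gata2 had 0.70 (0.247).

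Myeloid and progenitor genes mostly moved down where they passed. Of 18 myeloid and macrophage genes tested, 7 fell, such as Coro1a (-3.01), and 2 rose, Csf2rb (3.74), a receptor chain of myeloid cytokines, and Plek (1.36). Fcgr2b, an Fc receptor gene, was listed at 0 in both day 5 libraries after 6.38 and 4.6 FPKM on day 0. Nr1h3 had a log2 fold change of 0.37 (limma adjusted p = 0.428). Csf1r was listed at 0 in all 4 libraries, and Kit in 3 of 4. Of 11 stem and progenitor genes, 3 fell: Myb (-4.68), Sfpi1 (-4.28) and Ikzf1 (-0.93). Adjusted over the list alone, 2 myeloid genes rose and 8 fell, and 4 progenitor genes fell. Camera gave both lists a lower rank on day 5, with adjusted p of 0.0165 for myeloid and 0.0392 for progenitor genes, and of 0.553 and 0.362 with an estimated correlation. By fry the adjusted p was 0.0968 and 0.0217. The myeloid list did not pass camera at a filter of 5 FPKM (0.0544) or without day 5 replicate 1 (0.0707). The progenitor list did not pass with no filter (0.104), with quantile normalization (0.05002), without day 0 replicate 2 (0.092) or without day 5 replicate 1 (0.0849). Of 8 megakaryocyte genes, Itga2b alone passed and rose (3.09), with 2 rising adjusted over the list alone. Among the few genes tested of other cell types, the mast cell gene Hdc fell (-2.69, 1 tested), as did Thy1 of 3 lymphoid genes, and Vim (-4.06) and Thy1 of 3 fibroblast and epithelial genes. Thy1 was listed at 0 in both day 5 libraries after a mean of 3.81 FPKM. Adjusted over the list alone these counts were the same.

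Of 47 Myc and ribosome biogenesis genes, 32 fell and 0 rose (41 fell adjusted over the list alone), among them the nucleolar gene Nolc1 (536 ± 22.0 to 135 ± 2.56 FPKM), Nip7, Mybbp1a and Wdr43, with a list median of -1.06. Myc itself fell from 160 ± 16.0 to 76.6 ± 6.68 FPKM. Of 38 DNA replication genes, 8 fell and 0 rose (14 fell adjusted over the list alone), such as the licensing factor Cdt1 (-1.46) and Mcm3 (-1.04), and Pold1 and Rfc3 had -0.99 and -0.92. Of 40 mitosis genes only the phosphatase gene Cdc25b passed, and it rose (2.28), also adjusted over the list alone. Of 20 CDK inhibitor and growth arrest genes, 9 rose and 0 fell (10 rose adjusted over the list alone), including Btg2, Mxd4, Gadd45a (3.50) and Gadd45g (1.78). Of 15 genes of the G1 phase, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.15 and a mean of 0.14. Ccnd2 had 1.36, Cdk6 -1.46 and Cdc25a -1.01, while Rb1 had 2.89 with day 5 libraries at 333 and 88.3 FPKM (1.94 without day 5 replicate 1 and 3.84 without replicate 2). Camera's adjusted p was 1.01e-19 for ribosome biogenesis, 2.66e-06 for replication, 0.00078 for growth arrest, 0.799 for mitosis and 0.623 for G1 genes. With an estimated correlation the adjusted p of the first 3 was 0.197, 0.26 and 0.362, and by fry it was 0.0023, 0.0015 and 0.0217.

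Some genes of sugar breakdown and of stress responses fell as well. Of 19 glycolysis genes 9 fell and 0 rose, among them Pklr (-2.82), Hk2 (-2.10), Slc2a1 and Ldha (1059 ± 336 to 296 ± 22.0 FPKM). Of 22 heat shock and unfolded protein response genes 12 fell and 0 rose, such as the chaperone genes Hspe1 (-1.93), Hsp90aa1 (-1.46), Hspd1 (-1.43) and Sdf2l1 (-1.17). Of 28 mitophagy and autophagy genes 15 rose, including Map1lc3a (3.21) and Wipi1 (2.01), and Bnip3, a mitophagy receptor gene, fell (-1.77). Adjusted over the list alone, 15 glycolysis genes fell and 1 rose, 12 heat shock genes fell and 1 rose, and 15 mitophagy genes rose and 1 fell. Camera's adjusted p was 5.66e-07, 2.48e-05 and 0.00099 in this order, and 0.435, 0.267 and 0.435 with an estimated correlation. By fry it was 0.0874, 0.0225 and 0.0318, so glycolysis did not pass there.

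**Figure D2:**
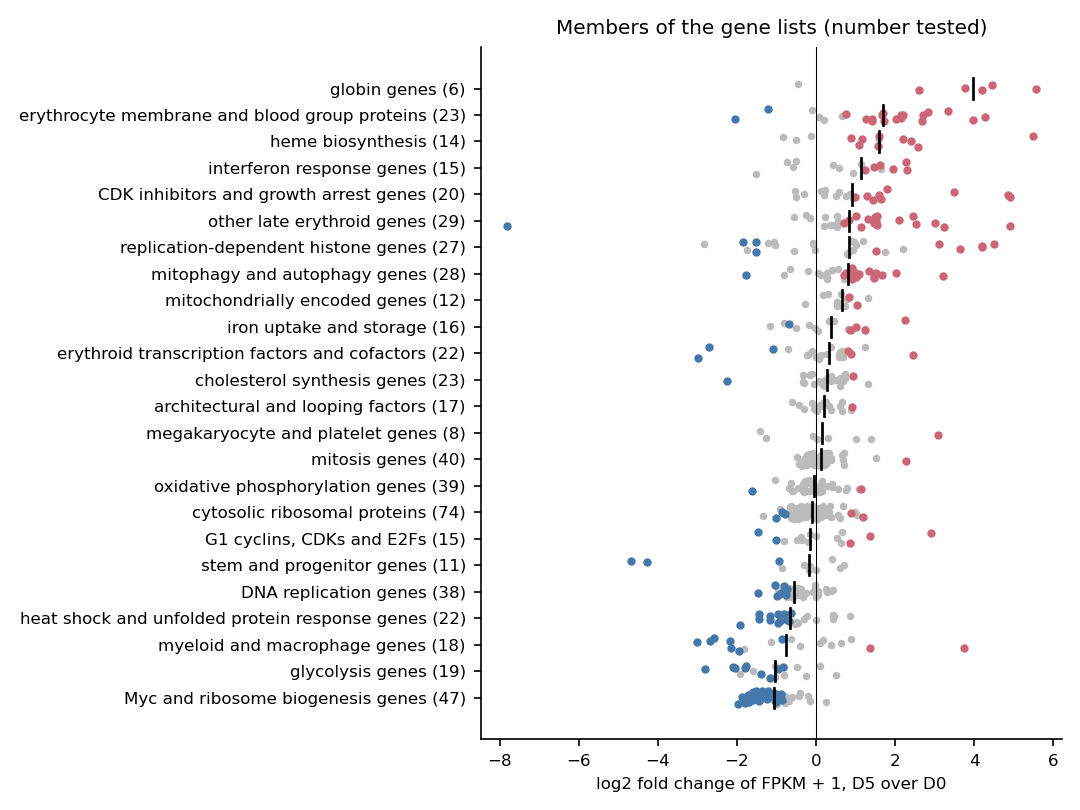
Log2 fold change of FPKM + 1 (day 5 over day 0, horizontal axis) of each tested member of the gene lists with at least 6 members, where red and blue points passed the threshold upward and downward, grey points did not, and black bars are list medians. The list medians run from -1.06 for Myc and ribosome biogenesis genes to 3.98 for globin genes.

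PU.1 binding was mapped to ask where the factor sits on both days. Day 0 had 14064 peaks and day 5 had 3530 in the lists merged over replicates. Of the day 0 peaks 3266, or 23.2% (95% interval 22.5 to 23.9), overlapped a day 5 peak of the merged list, and 10798 did not. Counting a peak in either single day 5 replicate, 9873 of the 14064, or 70.2% (69.4 to 70.95), had one, so most day 0 peaks missing from the merged day 5 list had a peak in at least 1 day 5 replicate. Nearly all day 5 binding lay at day 0 sites: 3280 of 3530 peaks, 92.9% (92.0 to 93.7), overlapped a day 0 peak, and only 31 had no peak in either day 0 replicate. With the same number of top ranked peaks taken from each day, 64.1% of day 0 peaks and 64.5% of day 5 peaks were shared. With 1 replicate standing for its day, a longer list, the shared share of day 0 peaks was 7.55% without day 0 replicate 1, 9.98% without day 0 replicate 2, 67.8% without day 5 replicate 1 and 46.8% without day 5 replicate 2. That of day 5 peaks was 98.9%, 98.2%, 52.5% and 62.4% in this order. The single replicates held 34590 and 46077 peaks on day 0 and 10714 and 18614 on day 5. These means, 40334 ± 8123 and 14664 ± 5586 (SD, n = 2), gave an exact two-sided permutation p of 0.333, the smallest that 2 against 2 allows. Median fold enrichment, the authors' value per peak, was 7.16 and 5.89 on day 0 and 5.54 and 5.67 on day 5.

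The chance of being found on day 5 followed the day 0 score. In the lowest decile of day 0 peaks by score 1.28% (0.811 to 2.01) were found on day 5, and in the highest decile 88.1% (86.3 to 89.7). The peak with the highest day 0 score lay on chromosome 1 from 194886297 to 194886797 (mm9) and was also found on day 5, although it lay in a DNase site on day 0 alone. The next 4, on chromosome 12 (77419746 to 77420317), chromosome 9 (48366651 to 48367258), chromosome 19 (8094388 to 8094969) and chromosome 7 (20456450 to 20457036), were bound and open on both days. The 5 highest on day 5 were likewise bound and open on both days. They lay on chromosome 19 (47207556 to 47207985), chromosome 7 (3849671 to 3850021), chromosome 11 (55344297 to 55344641), chromosome 7 (20456523 to 20457014, at the site of the fifth day 0 peak) and chromosome 1 (136616235 to 136616608).

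**Figure D3:**
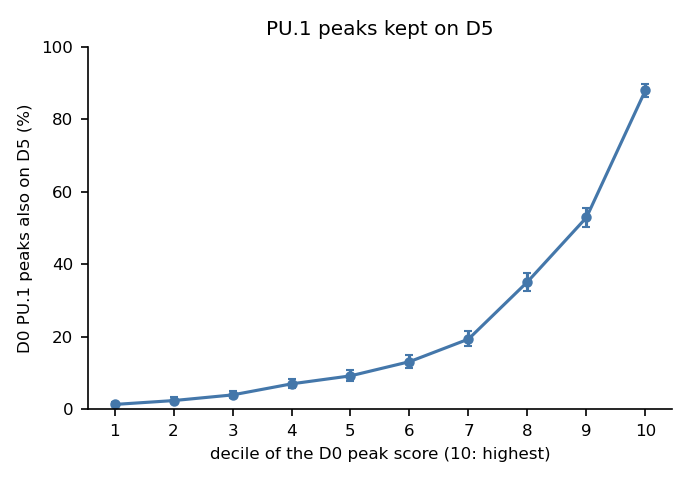
Percentage of day 0 PU.1 peaks that overlap a day 5 peak (vertical axis) by decile of the day 0 score (horizontal axis, 10 highest), with 95% Wilson intervals. The share runs from 1.28% in the lowest decile to 88.1% in the highest.

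PU.1 peaks lay mostly in open chromatin. Of day 0 peaks 81.8% (81.1 to 82.4) overlapped a day 0 DNase site, against at most 6.72% in 100 random placements. Of day 5 peaks 78.1% (76.7 to 79.5) overlapped a day 5 site, against at most 7.99%. A day 0 footprint was found in 47.8% of day 0 peaks and a day 5 footprint in 49.04% of day 5 peaks. Of 8538 peaks in a day 0 DNase site that were missing from the merged day 5 list, 5838, or 68.4% (67.4 to 69.35), also overlapped a day 5 site. Of 2964 peaks in a day 0 site found on both days, 2604, or 87.9% (86.6 to 89.0), did so, a comparison that is not matched for the score of the site. Counted by DNase site, those with a PU.1 peak on day 0 alone stayed open on day 5 in 72.1% (71.1 to 73.1). The share was 79.6% for sites with no peak, weighted to the same deciles of day 0 site score. Scores can still differ within a decile. The difference turned with the score of the site: in decile 6 these shares were 37.8% (34.5 to 41.2) and 62.2% (61.3 to 63.0), and in decile 10 they were 99.7% (99.3 to 99.8) and 95.03% (94.6 to 95.4). Sites with a peak on both days stayed open in 88.85%, against 88.87% for sites with no peak weighted to their deciles. This average also joins opposite differences, with 48.2% (40.2 to 56.4) in decile 6 and all 1210 sites in decile 10.

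DNase-seq asks which regions are open on each day. The intersected lists held 147639 sites on day 0 and 263887 on day 5, and covered 98.8 Mb and 92.2 Mb. Sites of single replicates covered 123.5 and 171.7 Mb on day 0 and 217.1 and 177.7 Mb on day 5, so covered length was not lower on day 5 there. Of the day 0 sites 59.3% (59.0 to 59.5) overlapped a day 5 site, and of the day 5 sites 37.5% (37.4 to 37.7) overlapped a day 0 site. In the list consolidated over both days, 85934 sites overlapped sites of both days, 60125 of day 0 alone and 164801 of day 5 alone. The added day 5 sites were weak: the median score was 3.45 for sites on day 5 alone and 9.32 for shared ones, and on day 0 it was 4.2 and 32.9. In the highest decile by score 96.1% of day 0 sites and 98.5% of day 5 sites were shared.

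Single replicates held 190924 and 252611 sites on day 0 and 617606 and 518066 on day 5, while sites with a score of at least 10 numbered 70618 and 70379 on day 0 and 45756 and 49959 on day 5. The exact permutation p was 0.333 for both, the smallest possible. Median site widths were 355 bp in both day 0 replicates and 260 and 243 bp on day 5. When 1 replicate stood for its day, the shared share ran from 42.1% to 71.1% of day 0 sites and from 18.6% to 48.1% of day 5 sites, the latter being 21.8% without day 5 replicate 1 and 18.6% without day 5 replicate 2.

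**Figure D4:**
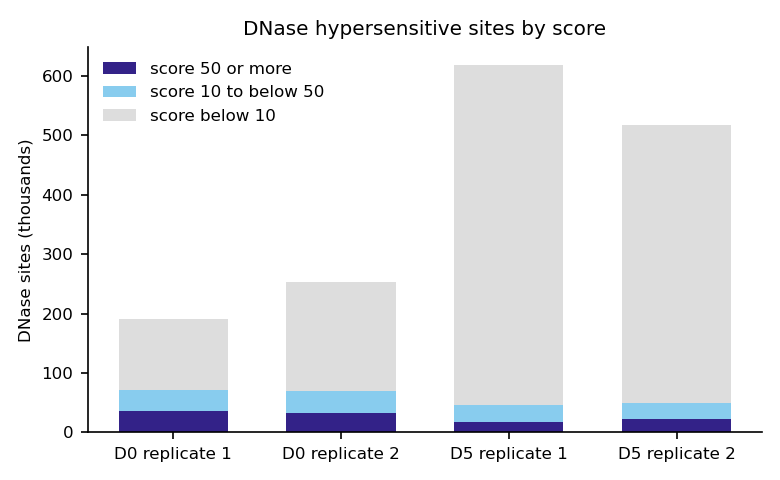
Number of DNase hypersensitive sites (vertical axis, divided by 1000) in each replicate, split by the authors' score into below 10 (grey), 10 to below 50 (light blue) and 50 or more (dark blue). Day 5 replicates have more sites in all, 617606 and 518066, and fewer with a score of at least 10, 45756 and 49959.

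Footprints, short protected stretches inside open sites, were similar in number, with 155765 on day 0 and 158217 on day 5. Of these 74.3% (74.1 to 74.5) of day 0 and 72.5% (72.3 to 72.8) of day 5 footprints overlapped one of the other day. Among the 40062 day 0 footprints without a day 5 partner, 85.8% lay in a site that was open on day 5, and 95.5% of the 43453 unpartnered day 5 footprints lay in a day 0 site. Unpartnered footprints had scores nearer the limit of -20, with medians of -25.1 on day 0 and -24.2 on day 5, against -51.7 and -52.9 for shared ones.

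ChIA-PET with an antibody against RNA polymerase II was used to compare contacts between vertices. These were built from DNase sites, polymerase II peaks and cohesin peaks, so a vertex need not be bound by the polymerase. The 1 kb vertices carried 4776 edges on day 0 and 4618 on day 5, of which 1807 were the same on both days, 37.8% (36.5 to 39.2) of day 0 and 39.1% (37.7 to 40.5) of day 5 edges. Of 130283 vertices 5084 had an edge on day 0, 5222 on day 5 and 3014 on both. Edges within a chromosome were shorter on day 5, with a median span of 38.5 kb against 45.0 kb. Edges over 100 kb made up 29.3% (28.1 to 30.6) of those on day 0 and 19.6% (18.4 to 20.7) on day 5. The median span was 59.5 kb for edges on day 0 alone, 41.6 kb for edges on day 5 alone and 33.7 kb for shared ones. With 3 kb vertices 14259 edges on day 0 and 10563 on day 5 shared 5370, and 29.9% and 22.7% spanned over 100 kb. Each day has 1 list, so the difference has no replicate check.

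**Figure D5:**
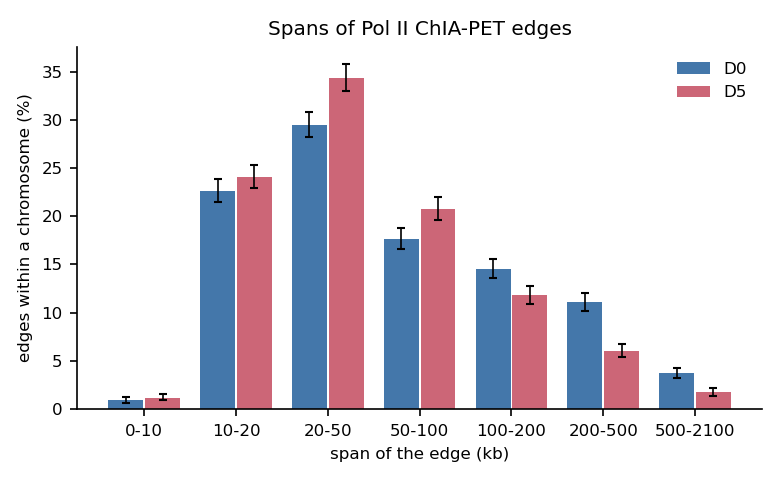
Percentage of ChIA-PET edges within a chromosome (vertical axis) by span in kb (horizontal axis) on day 0 (blue) and day 5 (red), with 95% Wilson intervals for counting error. Spans of 200 to 500 kb hold 11.1% of day 0 and 6.0% of day 5 edges.

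The vertex with the most edges on day 0, on chromosome 3 from 96359898 to 96369002, had 28 edges on day 0 and 20 on day 5. The others in the day 0 top 5 had fewer edges on day 5 too, which their selection by day 0 edges can give by itself. The vertex on chromosome 19 from 46102058 to 46120962 had 25 and 10, and those on chromosome 3 from 95732020 to 95736530 and from 96022507 to 96027436 had 23 and 13, and 22 and 7. The vertex on chromosome 15 from 97672987 to 97681900 had 20 and 7. On day 5 the vertex on chromosome 19 from 29322812 to 29329588 had 20 edges after 18 on day 0, and that on chromosome 3 from 95461982 to 95465410 had 18 after 17. The vertex on chromosome 10 from 79576750 to 79579157 had 15 after 3, and that on chromosome 15 from 31457935 to 31466621 had 14 after 8. These vertices are wider than 1 kb, at 2408 to 18905 bp, so width may add to their edge counts, which was not tested.

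The edge with the highest score on day 0 joined 2 vertices on chromosome 4, from 116860657 to 116865032 and from 116874155 to 116875980. Other top edges of day 0 lay on chromosome 1, where the vertex from 72300267 to 72303780 was joined to those from 72288900 to 72291735 and from 72272046 to 72274537. A further one on chromosome 3 joined 96022507 to 96027436 with 96039838 to 96042563. The remaining one joined chromosome 19, from 35377372 to 35379316, with chromosome 11, from 114527735 to 114532596. All 5 were also in the day 5 list. The top day 5 edge lay on chromosome 3, between 103593202 to 103597067 and 103612135 to 103614465. The next 4 joined vertices on chromosome 7 (from 16879423 and 16893697), chromosome 11 (from 102974659 and 102992936), chromosome 8 (from 108324591 and 108344620) and chromosome 1 (from 135973912 and 135994887). Of these 5 the one on chromosome 11 was absent from the day 0 list.

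PU.1 peaks were common at connected vertices. A day 0 peak lay in 27.2% of 5084 vertices with day 0 edges and in 6.86% of 122991 vertices without an edge. Among vertices of exactly 1000 bp, where width cannot differ, these shares were 9.47% and 4.39% (Fisher odds ratio 2.28, adjusted p = 0.00078). They came from 25 of 264 and 4206 of 95887 vertices. Day 0 DNase sites were also more frequent at the connected ones of this width (96.2% against 66.3%), as were day 0 footprints (56.1% against 30.1%). The PU.1 difference was therefore not separated from openness. The share with a day 0 peak did not differ between vertices with edges on day 0 alone and on day 5 alone. It was 23.4% and 22.8% (Fisher odds ratio 1.04, adjusted p = 0.849). A day 0 peak missing from the merged day 5 list was less common at vertices with edges on day 0 alone (16.6%) than on both days (21.5%; odds ratio 0.727, adjusted p = 3.58e-05). Widths differ there, and among vertices of exactly 1000 bp the direction turned and did not pass (14 of 209 and 2 of 55, odds ratio 1.90, adjusted p = 0.804). Vertices open on day 0 alone were more frequent among those with edges on day 0 alone (39 of 2070) than on day 5 alone (9 of 2208; odds ratio 4.69, adjusted p = 9.86e-06). For vertices of exactly 1000 bp these were 31 of 209 and 8 of 278 (odds ratio 5.88, adjusted p = 8.00e-06). The mirror comparison did not pass: vertices open on day 5 alone numbered 12 of 2208 with edges on day 5 alone and 10 of 2070 with edges on day 0 alone (odds ratio 1.13, adjusted p = 0.909).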

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

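Tests with mitochondrially encoded genes removed and with ChIA-PET edges chosen by score were added after the data were seen. The count of 1989 genes stayed within 1.5 times under the other pseudocount, the higher filter, quantile normalization, removal of globin or of mitochondrially encoded genes and a minimum log2 fold change of 1, at 1585 to 2120. With no filter it was 237 of 15168 genes, of which 182 were among the 1989, and the cause was not tested. Leaving out 1 library gave 0 to 13 genes, since 1 residual degree of freedom remained. With the replicate block the count was 1797. Same-numbered libraries hardly deviated together across genes (correlation of deviations 0.048). With 2 libraries per day the deviations mirror each other, so both pairs give this same value. It cannot show that the samples were unpaired, and the main fit did not use the numbers to pair them. Of 26 lists tested, 15 passed camera, 12 to 15 under the other settings, and 0 with an estimated correlation. The replicate block ended 1 of these calls, cytosolic ribosomal proteins (adjusted p = 0.0558), and those of 8 named genes: Pcbp1 (0.0516), Klf3 (0.056), Med13 (0.0579), Mvk (0.0685), Irf7 (0.0509), Rpl10 (0.0516), Rps24 (0.0559) and mt-Cytb (0.0608). The direction turned for oxidative phosphorylation genes with quantile normalization (adjusted p = 0.203), for histone genes without day 5 replicate 2 (0.92, range 0.0849 to 0.92 with 1 library left out) and for Yy1 without day 5 replicate 1 (log2 fold change 0.16, range -1.01 to 0.16), none of them called there. Of 97 named genes 68 no longer passed without the filter, 10 with quantile normalization (Pcbp1, Cd24a, Klf3, Med13, Mvk, Sdf2l1, Irf7, Irf9, Rpl10 and mt-Cytb), 6 with the pseudocount of 0.1 (Anxa2, Pcbp1, Sdf2l1, Ddx58, mt-Nd6 and mt-Cytb) and 1 with globin genes or mitochondrially encoded genes removed (Pcbp1), all with direction kept, while 2 newly passed with quantile normalization (Gata1 and Klf1) and 1 at the higher filter (Klf1). The shared shares below are given for day 0 and then day 5, with cause not tested. For PU.1 peaks they were 16.5% and 65.8% with 50% reciprocal overlap, 24.7% and 98.6% in the stricter 50% of peaks, 25.6% and 93.8% for replicate 1 peaks overlapping replicate 2, and 64.1% and 64.5% with equal numbers. With 1 replicate left out they ran from 7.55% to 67.8% and from 52.5% to 98.9%, since the peaks of a single replicate are a longer list than the merged one. For DNase sites they were 37.8% and 21.2% with 50% overlap and 49.97% and 55.4% with equal numbers, and ran from 42.1% to 71.1% and from 18.6% to 48.1% with 1 replicate left out. For footprints they were 65.6% and 64.6% with 50% overlap and 80.6% and 78.8% in the stricter 50%. PU.1 peaks at least 50% covered by DNase sites of their day made up 78.3% and 74.6%. ChIA-PET edges were shared at 50.8% of day 5 edges with 3 kb vertices, at 35.2% and 37.3% for edges of at least 20 kb, and at 35.7% and 36.9% in the top 50% by score. Median spans were 41.4 kb on day 5 with 3 kb vertices, 69.2 kb and 54.7 kb for edges of at least 20 kb, 43.3 kb on day 0 with equal numbers, and 31.2 kb and 29.3 kb in the top 50%. The 95% intervals of the last pair overlap (29.65 to 32.7 and 28.1 to 30.7), so the spans were not clearly apart among the edges with the highest scores. Alternatives by the number of paired tags were not run, since the lists hold a score, and those for genes near peaks or edges were not run for lack of an mm9 annotation. Depth is unknown for all files, which limits what the loss of weak peaks and edges can show.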

Other observations

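Every test of an explanation for the patterns of PU.1 peaks, DNase sites and ChIA-PET edges was chosen only after the result, or a close relative of it, was seen, except that on edges between vertices connected on both days. Several lists beyond those above held called genes. Of 15 interferon response genes 6 rose and 0 fell on day 5, among them Isg15 (log2 fold change 2.29), Ddx58 (2.27), Irf7 (1.95) and Irf9 (1.61), and the list did not pass camera (adjusted p = 0.129). Of 27 replication-dependent histone genes 6 rose and 3 fell, with Hist2h2aa2 at 4.18, Hist1h2ao at -1.52 and Hist1h4i at -1.85, and near-identical copies make single members uncertain (camera adjusted p = 0.39, and 0.0492 at a filter of 5 FPKM). Of 74 ribosomal protein genes 2 rose, including Rpl39 (0.87), and 3 fell, including Rpl10 (-1.02) and Rps24 (-0.87), with a camera adjusted p of 0.0307 that was 0.675 with an estimated correlation, 0.494 after quantile normalization, 0.312 without day 0 replicate 1 and 0.103 without day 5 replicate 1 (fry 0.498). Adjusted over the list alone, 8 interferon genes rose and 2 fell, 7 histone genes rose and 4 fell, and 0 ribosomal protein genes passed in limma (11 at an unadjusted p under 0.05). Of 39 oxidative phosphorylation genes Ndufa2 rose (1.14) and Atp5g1 fell (-1.62), with an adjusted p of 0.17 and an opposite direction after quantile normalization. Of 23 cholesterol synthesis genes 1 rose, Mvk (0.94), and 1 fell, with an adjusted p of 0.455. Of 12 mitochondrially encoded genes 2 rose, mt-Nd6 (1.03) and mt-Cytb (0.82), with an adjusted p of 0.0307 that was 0.435 with an estimated correlation, 0.0978 with no filter, 0.125 without day 0 replicate 1 and 0.168 without day 5 replicate 2 (fry 0.0726). Megakaryocyte (0.623), lymphoid (0.482) and erythroid transcription factor genes (0.623) did not pass camera, nor did fibroblast and epithelial genes with an estimated correlation (0.0165 preset, 0.362 estimated) or with no filter (0.0501), with a fry adjusted p of 0.0315.

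Chosen after their values were seen, Xist stood at 104 ± 9.13 FPKM on day 0 and 152 ± 7.48 on day 5 beside the Y-linked genes Eif2s3y (47.3 and 41.3 FPKM) and Ddx3y (20.2 and 18.7 FPKM) in the same MEL libraries, and none of the 3 passed limma (adjusted p = 0.07, 0.521 and 0.91). In windows of 1 Mb, also looked at afterwards, the largest loss of edges lay on chromosome 13 from 23000001 to 24000000, with 62 on day 0 and 31 on day 5, and the largest gains were on chromosome 12 from 32000001 to 33000000, with 1 and 23, and on chromosome 1 from 75000001 to 76000000, with 23 and 45. Edges between chromosomes numbered 22 on day 0 and 21 on day 5, and 4 were found on both days.

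PU.1 peaks numbered 14064 on day 0 and 3530 on day 5, while Sfpi1 mRNA fell. A uniformly weaker day 5 ChIP, whether from less protein or from a poorer or shallower library, cannot be told apart from site-specific loss. With equally many top ranked peaks per replicate, overlaps across days averaged 62.7% (57.9% to 67.8%), close to the 63.96% of the day 5 pair and below the 83.3% of the day 0 pair. Of peaks in a day 0 DNase site and missing from the merged day 5 list, 68.4% (67.4 to 69.35) also lay in a day 5 site. This argues against complete closing of the site for most of these peaks. Partial closing is not addressed, since a site of any score of at least 2 counts as open. Missing from the merged list also does not mean unbound, as 70.2% of all day 0 peaks had a peak in at least 1 day 5 replicate. Whether closing accompanies loss of the peak stays a hypothesis. Within deciles of the day 0 score, the odds ratio for keeping the peak in a day 5 DNase site was 2.69 (95% interval 2.40 to 3.03). It covers all 14064 day 0 peaks, of which only 11502 lay in a day 0 site, so it does not measure closing alone. More ready peak calling in open chromatin may also give it.

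Day 5 had more but weaker DNase sites. The tables argue against splitting of day 0 sites as the whole cause, since there were 1.13 day 5 sites per shared day 0 site where the ratio of list lengths was 1.79. Chance calls that never recur are also argued against as the whole cause in single replicates. Of day 5 replicate 1 sites with a score under 10, 35.9% were found in replicate 2. This was at most 13.5% in 10 random placements, and 60.4% for the day 0 counterpart. The intersected lists hold only recurring sites by construction. Sites with a score of at least 10 numbered on day 5 0.679 times those on day 0. Deeper libraries alone would not give this if the score rises with depth. That was not checked, so depth is not excluded. A lower signal over background with a permissive limit and a broad, weak opening of chromatin both stay open, since read depth is unknown.

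Long ChIA-PET edges were fewer on day 5. Vertices connected on 1 day alone do not account for all of it in these lists. Among edges between vertices connected on both days, 28.8% (27.1 to 30.5) spanned over 100 kb on day 0 and 20.7% (19.2 to 22.4) on day 5. These vertices can still differ between the days in how many edges each carries, so a shift of edges among them is not excluded. Whether weak edges account for it could not be decided, since the definition of the score is unknown. In the 50% of each list with the highest scores, 16.3% (14.9 to 17.8) of edges spanned over 100 kb on day 0. On day 5 it was 10.5% (9.28 to 11.8), so the difference in this share held among the edges ranked highest. The median spans of these edges, 31.2 kb and 29.3 kb, were not clearly apart. A difference in library depth or ligation noise between the days may remain, as each day has 1 list and no paired tag counts, so a loss of long contacts is only a hypothesis.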
